A study of Mus musculus with 2 samples.

How the data were processed

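Midbrain was taken from mouse embryos of strain B6NCrl at 15.5 days of development and profiled by chromatin immunoprecipitation with an antibody to H3K27ac followed by sequencing. Per the labels, the series holds 2 biological replicates of 1 group, with sexes mixed, from 78 embryos (replicate 1) and 62 embryos (replicate 2), and libraries of 300 to 500 bp. There was no second tissue, age or mark, so no groups of samples were compared.

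The starting point was 4 peak lists that the authors deposited in narrowPeak format on mouse assembly mm10. Per the deposited records, 1 list was called on replicate 1 alone and 1 on replicate 2 alone, each with its own control alignments. A pooled list was called on the joined alignments of both replicates with both controls. A replicated list was derived from both replicate lists and the pooled list, by a rule that the deposited records do not state. The aligner, the peak caller and their versions are not given in the sources used here. The deposited score of each peak is a display value between limits set within its list, and was not used. The deposited signal value of each peak is the authors' own measure against control, on a scale that is not stated. The deposited −log10 p and −log10 q values are the authors' significance of each peak against control, and every list started at a −log10 p close to 2. The deposited summit position is counted in bp from the start of the peak. Signal values were used to describe, rank or filter peaks within a list. Values of the same locus in the lists of both replicates were set side by side, and a difference between the lists was not read as a change. The lists hold no read counts, so the sequencing depth behind each replicate is unknown and no interval that needs it was computed.

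Peaks on the assembled chromosomes were used, which left out 8 of 51826 replicated peaks. Genes were the 21911 protein-coding genes of GENCODE M21 on the same assembly, and sequence came from RefSeq GRCm38.p6. The transcription start site (TSS) of a gene was its annotated 5′ end. A gene had a promoter peak where a replicated peak overlapped the 1 kb on either side of the TSS by at least 1 bp. Other peaks were called distal and were assigned to the gene with the nearest TSS. The acetylated length of a gene was the number of bases under peaks within the gene body and 10 kb on either side, given as the mean and SD of the lists of both replicates, and it can include peaks of neighbouring genes. It was not divided by gene length, so long genes can rank above short ones. Genes called most or least acetylated are ranked by this acetylated length. Clusters joined replicated peaks within 10 kb of each other and were ranked by the bases under their peaks.

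Overlap between replicates was the share of peaks overlapped by at least 1 bp, and the Jaccard index of the bases covered, against 100 circular shifts of 1 list along each chromosome (one-sided). The correlation of signal values was taken across peaks, which are not independent replicates, so it carries no p. For 22 gene lists, promoter peaks of the members were compared with those of all other protein-coding genes by two-sided Fisher's exact tests, and distal peaks by a two-sided permutation test against 10000 random lists of the same size, matched on the length of the territory nearest to each TSS in 10 bins. Both families were adjusted by Benjamini-Hochberg over the 22 lists at 0.05. The midbrain patterning list was compared with the forebrain patterning and Hox lists, and the neural lists (progenitor, pan-neuronal, midbrain patterning, dopaminergic, GABAergic, glutamatergic and tectal) with the non-neural lists (liver, cardiac muscle, skeletal muscle, epidermal, erythroid), by two-sided Fisher's exact tests without shared members. Genes were the units of these tests, so the p-values describe how lists differ within these libraries, not how animals vary. Members were treated as independent, whereas the Hox genes lie side by side in clusters, so the p-values of that list overstate the evidence. Per-sample columns left unused numbered 0. Of the listed genes, Ahsp was not found in the annotation. Some genes stand in more than 1 list: En1, En2, Lmx1b, Gata2, Gata3, Tal1, Tal2, Helt, Pou4f1, Dlx1 and Dlx2.

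Sites of 16 motif consensus sequences were counted on both strands in 1 kb windows at the midpoints of distal replicated peaks on 19 autosomes, and in flanks 5 kb away that overlapped no pooled peak. The ratio of site densities had a 95% interval from 1000 bootstrap draws over autosomes, and was compared with up to 20 permutations of the letters of each consensus. A motif was called higher where the interval lay above 1 and the ratio lay above that of every permutation with at least 20 flank sites. This calling rule was not part of the plan made before the data were examined: it was written into the script before motif results were seen, and the minimum of 20 flank sites was added after a first run stopped with warnings of permutations without flank sites. A motif with fewer than 20 flank sites of its own could not be called, a rule added after results were seen that covered HNF1 with 500 bp windows and among the 50% of peaks with the highest signal value, where it had not been called before. Promoters were called CpG-rich where the 500 bp on either side of the TSS had at least 50% GC and an observed to expected CpG ratio of at least 0.6.

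The gene lists, motif sequences, tests and all alternatives except those named as added later were fixed before the data were examined. The rule for genes named in the text was fixed then too. It took up to 4 members per list with the highest and the lowest rank of acetylated length, every member where 5 or fewer had or lacked a promoter peak, the 15 clusters with the most acetylated bases, the 10 widest and the 10 strongest replicated peaks, and Otx2, En1, En2, Pax7, Foxg1, Th, Slc6a3, Gata2, Sox2 and Tubb3. Members that tied at no acetylated bases were not named one by one.

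The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and were tested on simulated data. The interval functions were right for 100% of 10000 simulated intervals. Of 200 simulated lists of 20 genes among 21911, the promoter test at an unadjusted 0.05 called 4% when members and other genes had the same probability of a peak, 99% when members had a probability of 0.9 against 0.5, and 98.5% when they had 0.1. The distal test called 3.33% of 60 unchanged lists, 21.7% of lists raised 2-fold and 50% of lists raised 3-fold, with mean ratios of 1.03, 2.07 and 3.01, so a 2-fold excess in a list of this size was mostly missed. In 5 simulated genomes with 4 motifs planted in 15% of windows, 20 of 20 planted motifs were called higher, while 0 of 55 motifs that were not planted were called higher and 1 of 55 was called lower. Motifs with too few simulated flank sites to be called are not counted in these 55. The simulated bases were drawn at equal frequency, so peaks and flanks did not differ in GC or CpG content as they do in the data. These rates therefore do not cover false calls from base composition. An earlier simulation planted the CTCF consensus, which contains an E-box, and called the proneural E-box and the LIM and POU motif, neither of which was planted; ETS was planted in its place after that outcome, the number of simulated genomes was raised to 5, and the mean ratio replaced the median ratio in the distal simulation.

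Alternatives were promoter windows of 500 bp and 2 kb, every annotated transcript start, each replicate list alone, the pooled list, the 50% of replicated peaks with the highest signal value, the peak midpoint in place of any overlap, and distal peaks within 50 kb of a TSS. For overlap, they were a reciprocal overlap of 50%, a −log10 q of at least 5 and the top 20000 peaks. For clusters, they were joining distances of 5 and 20 kb. For motifs, they were 500 bp windows and windows centred on the summit. CpG-rich promoters alone, replicated peaks that overlap both replicate lists, and letter permutations with as many CG letter pairs as the consensus were added after seeing the data. Ambiguous letters that can match C or G were not counted in these pairs. The CpG content of matched sites can therefore still differ between such a consensus and its permutations.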

Results

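H3K27ac, a histone mark of active promoters and enhancers, was mapped in mouse midbrain at embryonic day 15.5 in 2 replicate pools of embryos that form a single group. Replicate 1 had 80799 peaks on the assembled chromosomes and replicate 2 had 90012, covering 43.6 and 53.5 Mb (1.60% and 1.96% of the genome). The pooled list had 98463 peaks. The replicated list, on which the results below rest unless stated, had 51818 peaks of 701 bp median width covering 52.4 Mb. Every replicated peak was identical to a pooled peak, 43670 (84.3%) overlapped peaks of both replicates, 7886 (15.2%) overlapped a peak of 1 replicate, and 262 overlapped neither. The sequencing depth of the replicates is unknown, because the lists hold no read counts.

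Strong peaks of either pool were found in the other. Every peak in the highest 10% of signal values in either replicate was overlapped by a peak of the other. Ranked by the signal value in the replicated list, the strongest peak lay at the promoter of Klf7, a zinc finger transcription factor needed for axon outgrowth (chromosome 1, 64115797 to 64123329), with a signal value of 62.8 ± 6.01 in the replicate lists (SD, n = 2). Next came peaks at Epc1, a subunit of the NuA4 histone acetyltransferase complex (46.9 ± 19.7), Arrdc3, an arrestin-domain protein (54.9 ± 11.7), the zinc finger factor Sp3 (47.3 ± 17.5) and Kansl1, a scaffold of the NSL acetyltransferase complex (52.9 ± 3.64). The other 5 of the 10 strongest peaks lay at Actg1, Cox20 and Hnrnpu, Atf1, Zc3h4 and Rev3l, with signal values of 44.9 to 53.3. Across all peaks, 68.0% of replicate 1 peaks and 55.2% of replicate 2 peaks were overlapped by the other replicate, against 3.69% and 3.24% after circular shifts (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). With a reciprocal overlap of 50%, the shares were 39.6% and 35.5%, and among the 20000 strongest peaks of each replicate they were 85.1% and 81.0%. Overlap was lower among weak peaks: 47.2% of replicate 1 peaks and 27.5% of replicate 2 peaks in the lowest 10% of signal values were overlapped. Over the 43670 replicated peaks found in both, the signal values had a Spearman rho of 0.789 and a Pearson r of 0.919 across peaks, and 81.2% of them lay within 1.5-fold of each other.

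**Figure D1:**
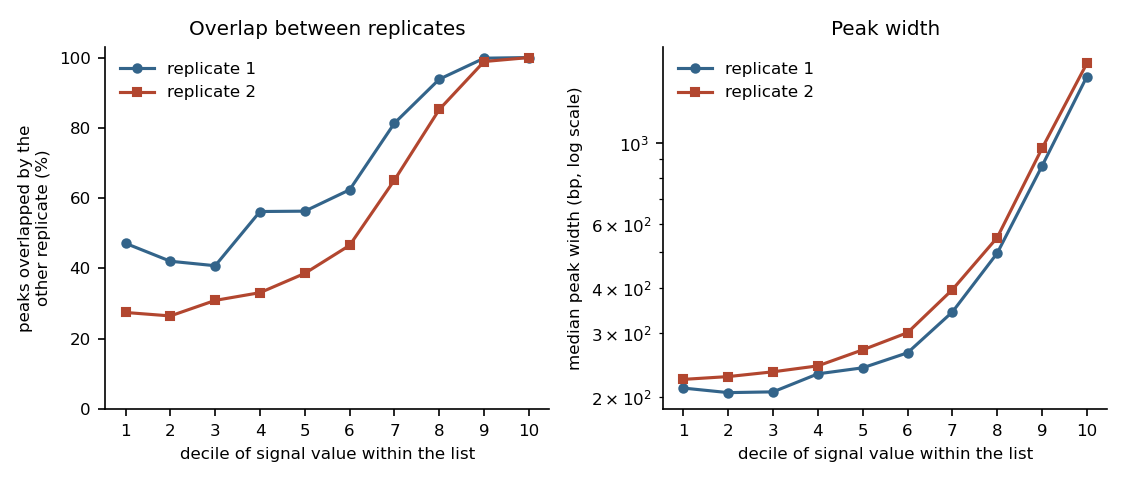
Left, the share of peaks (%) of each replicate overlapped by the other, against bins of signal value that each hold 10% of the list, from lowest (1) to highest (10); right, the median peak width (bp, log scale) of the same bins. Overlap reached 100% in the highest bin of both replicates, where peaks had median widths of 1519 and 1651 bp.

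Housekeeping genes and the genes shared by all neurons lay at the acetylated end of the promoters, and sensory receptor genes at the other. A promoter peak was found at 11452 of 21911 protein-coding genes (52.3%), at 11580 genes in replicate 1 and 11887 in replicate 2, with 11307 in both. Of 1134 olfactory receptor genes, which are expressed in the olfactory epithelium, 1 had a promoter peak, as did 1 of 330 vomeronasal receptor genes. Promoter peaks made up 23.0% of replicated peaks, and were wider (1252 bp median width) and stronger (median signal value 11.4) than distal peaks (611 bp and 3.57). Introns held 41.3% of the peaks, exons outside promoters 4.86% and intergenic sequence 30.8%. Shifted peaks fell in promoters in 2.46% of cases, in introns in 35.8%, in exons in 3.34% and in intergenic sequence in 58.4%. The distal peaks lay a median of 58.4 kb from the nearest TSS. The promoter share was 14.1% in the longer pooled list and 40.1% among the 50% of replicated peaks with the highest signal value.

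Neuronal and progenitor genes were acetylated at nearly every promoter. All 22 pan-neuronal genes had a promoter peak, against 52.2% of other genes (adjusted p = 7.82e-06, two-sided Fisher's exact test over 22 lists). Tubb3, the neuronal beta-tubulin (chromosome 8, 123411424 to 123422015), had a promoter signal value of 29.3 in replicate 1 and 29.6 in replicate 2. Acetylated length, which was not divided by gene length and so can favour long genes, was longest at 4 members. These were the RNA-binding proteins Celf4 (66.8 ± 13.1 kb of acetylated length; SD, n = 2) and Rbfox3 (41.0 ± 6.34 kb), the adhesion molecule Ncam1 (35.5 ± 7.76 kb) and the presynaptic receptor Nrxn1 (33.1 ± 3.69 kb). At the Rbfox3 promoter, the signal value was 2.66 in replicate 1 and 20.8 in replicate 2. The shortest acetylated lengths were those of Elavl3, Stmn2, Nefl and Syp (2.87 to 4.87 kb), all with a promoter peak. Among CpG-rich promoters alone, 12 of 12 pan-neuronal genes had a promoter peak against 88.2% of other genes (exact adjusted p = 0.670). No count above 12 of 12 was possible, so this test could not show an excess.

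Of 20 genes of neural progenitors and radial glia, 18 had a promoter peak (exact adjusted p = 0.00277). Sox2, a transcription factor that keeps neural stem cells undifferentiated (chromosome 3, 34650405 to 34652461), had promoter signal values of 14.3 and 12.5, and 16.3 ± 0.571 kb of acetylated length. The receptor Notch1 (23.8 ± 3.80 kb), the RNA-binding protein Msi1 (13.7 ± 1.40 kb) and Sox1 (11.3 ± 0.273 kb) were the other leading members. The members without a promoter peak were Pax6 and Neurog1, transcription factors of neurogenesis: Pax6 had a peak in replicate 1 alone (signal value 2.45) and was counted when every transcript start was used, and Neurog1 had a peak in replicate 2 alone (2.65). Neurog2, Sox3 and Prom1 were among the least acetylated members (1.45 to 3.07 kb), with a promoter peak each. With the peak midpoint required to lie within the promoter, 14 of 20 progenitor genes were counted (exact adjusted p = 0.106), and among CpG-rich promoters alone 13 of 14 had a peak (adjusted p = 1). A peak at all 14 would not have passed there either, so the restriction could not show an excess.

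**Figure D2:**
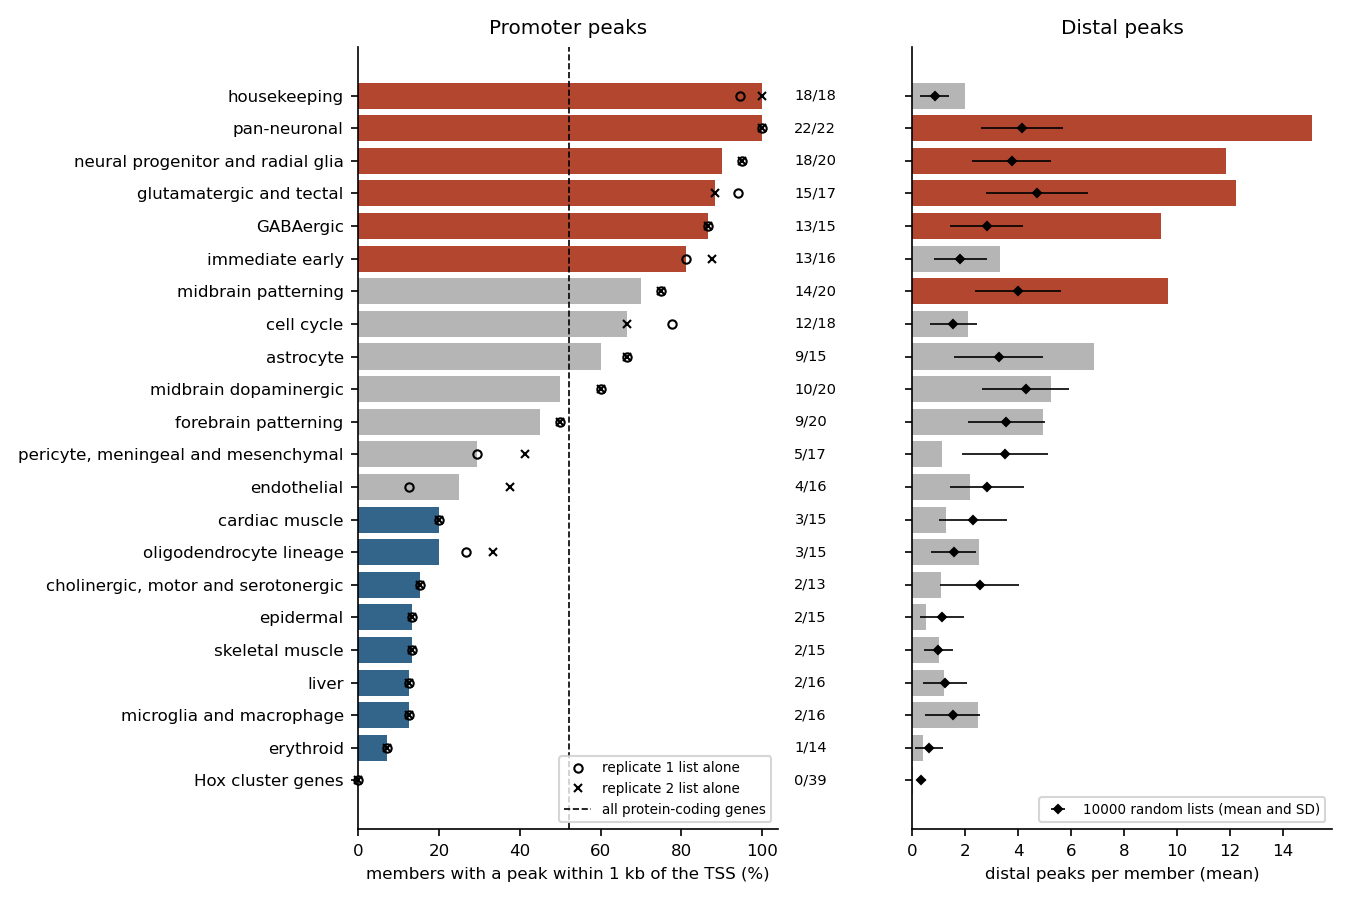
Left, the share of members (%) with a promoter peak in the replicated list (bars; counts at the right) and in each replicate list alone (circles and crosses), for 22 gene lists; the dashed line is the 52.3% of all protein-coding genes, and red and blue bars are lists higher or lower at an adjusted p under 0.05. Right, the mean number of distal peaks per member (bars, red where higher) with the mean and SD of 10000 matched random lists (diamonds); pan-neuronal genes had 15.1 against 4.15.

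Genes of both major neuron classes of the midbrain were acetylated. Of 15 GABAergic genes, 13 had a promoter peak (adjusted p = 0.0165), and of 17 glutamatergic and tectal genes, 15 did (adjusted p = 0.00670, both two-sided Fisher's exact tests). Among GABAergic genes, the transcription factors Tfap2b (18.997 ± 0.808 kb; SD, n = 2), Gata3 (19.1 ± 1.46 kb), Lhx5 (18.3 ± 0.00919 kb) and Lhx1 (16.2 ± 0.798 kb) had the longest acetylated lengths. Gata2, a selector of midbrain GABAergic identity (chromosome 6, 88193891 to 88207032), had promoter signal values of 4.68 and 6.24 and 2.74 ± 0.582 kb, among the lowest of the list with Dlx2, Tal2 and Helt. The GABAergic members without a promoter peak were Helt and Gad1, the GABA-synthesising enzyme. Gad1 had 12.4 ± 0.854 kb of acetylated length, and was counted when every transcript start was used. Among glutamatergic and tectal genes, the EBF transcription factors Ebf3 (44.2 ± 10.1 kb), Ebf1 (20.5 ± 7.66 kb) and Ebf2 (20.8 ± 4.56 kb) and the LIM factor Lhx9 (21.3 ± 1.104 kb) led. Neurod1, with a peak in replicate 1 alone (3.62), and the vesicular transporter gene Slc17a7 had no replicated promoter peak, and both were counted with a 2 kb window. Grin1, Bhlhe22 and Neurod6 were among the least acetylated (0.569 to 2.28 kb), with a promoter peak each. With the peak midpoint required, 8 of 15 GABAergic (exact adjusted p = 0.824) and 13 of 17 glutamatergic genes (adjusted p = 0.0644) were counted, and among the 50% of peaks with the highest signal value 10 of 15 GABAergic genes were (adjusted p = 0.243). Among CpG-rich promoters alone, neither list passed (8 of 9 and 9 of 10, both exact adjusted p = 1). A peak at every one of these promoters would not have passed either, so the restriction could not show an excess.

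Several genes that set midbrain identity carried promoter acetylation, whereas no Hox gene did. Otx2, which specifies forebrain and midbrain (chromosome 14, 48657677 to 48673819), had promoter signal values of 7.54 and 7.24. The engrailed genes, which pattern midbrain and anterior hindbrain, had 12.02 and 12.01 (En1, chromosome 1, 120602418 to 120607992) and 12.9 and 13.7 (En2, chromosome 5, 28165694 to 28172166). Pax7, a regulator of the dorsal midbrain (chromosome 4, 139737062 to 139833528), had 6.14 and 7.85. Meis2 (33.8 ± 3.72 kb; SD, n = 2), Gata3, Pax7 (18.8 ± 5.08 kb) and Otx2 (15.6 ± 2.20 kb) had the longest acetylated lengths of the midbrain patterning list. Its least acetylated members were Pax2 (2.34 ± 0.557 kb), the secreted signals Fgf8 (0.391 ± 0.0368 kb) and Wnt1 (0.214 ± 0.302 kb), and Helt, none with a promoter peak. A promoter peak was found at 14 of 20 midbrain patterning genes, a share that did not differ from that of all other genes past the threshold (exact adjusted p = 0.1498).

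None of the 39 genes of the Hox clusters, which pattern hindbrain and spinal cord, had a promoter peak, in the replicated list or in either replicate list (exact adjusted p = 6.32e-12). The midbrain and Hox lists differed by 70 percentage points (adjusted p = 5.83e-09, two-sided Fisher's exact test over 2 comparisons). Both p-values treat the Hox genes as independent, although they lie side by side in clusters, and so overstate the evidence. Of 20 forebrain patterning genes, 9 had a promoter peak (exact adjusted p = 0.687 against all other genes). They included Lhx2 (promoter signal values 24.0 and 20.0; 18.7 ± 1.56 kb), Six3 (13.04 ± 1.68 kb), Emx2 (7.75 ± 0.617 kb) and Dlx1 (4.79 ± 0.972 kb). Foxg1, a regulator of the telencephalon (chromosome 12, 49382660 to 49386861), had no replicated promoter peak and a signal value of 3.79 in replicate 1 alone, and was counted in the pooled list and with a 2 kb window. Lhx6, Lhx8, Rax and Six6 were among the members with the least acetylation, without a replicated promoter peak; Lhx6 had one in replicate 2 alone (3.34). The 25 points between the midbrain and forebrain lists did not pass the test (exact adjusted p = 0.200).

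**Figure D3:**
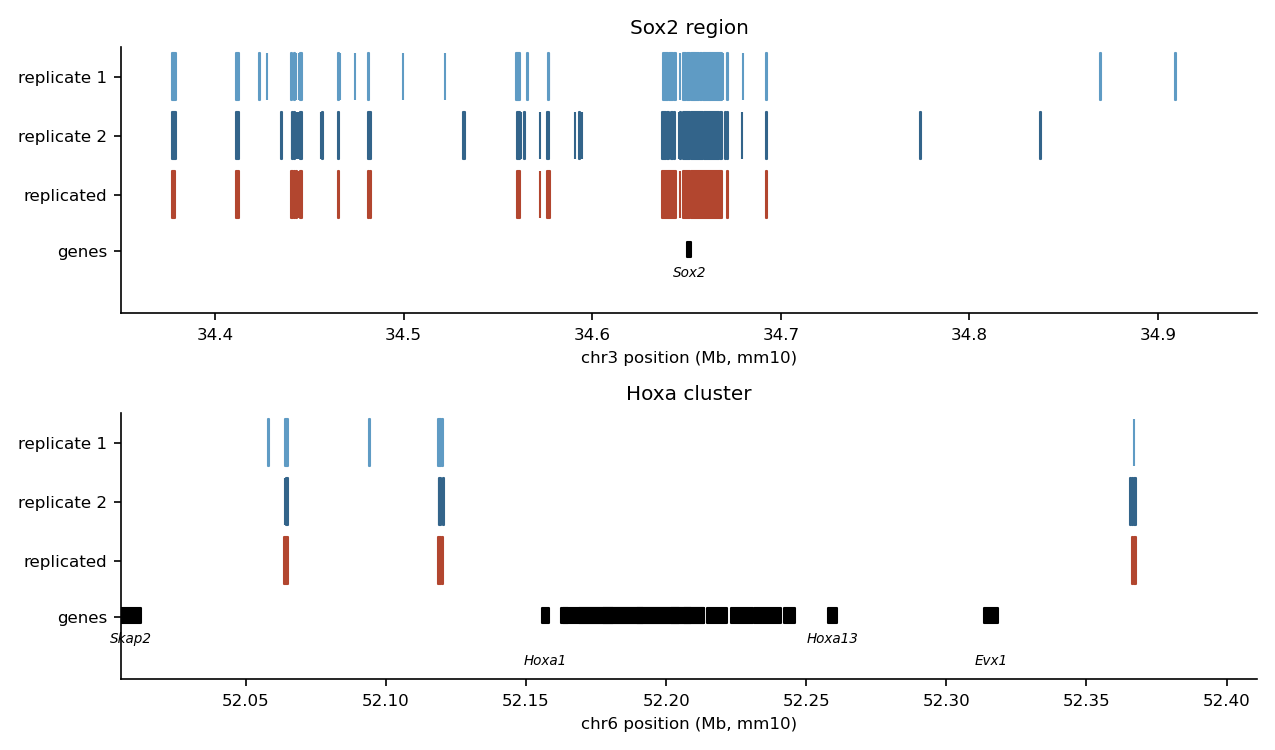
Peaks of replicate 1, replicate 2 and the replicated list (boxes) and annotated genes (black) along chromosome position (Mb, mm10), around Sox2 and across the Hoxa cluster. Acetylation covered Sox2 and its surroundings in both replicates, while no promoter of the Hoxa genes carried a peak.

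Dopaminergic genes were divided. Of 20 genes of midbrain dopaminergic neurons, 10 had a promoter peak (exact adjusted p = 1), among them the neurotrophic factor receptor Gfra1 (12.6 ± 2.34 kb; SD, n = 2), En1 and En2. Neither Th, the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892752 to 142931128), nor Slc6a3, the dopamine transporter (chromosome 13, 73536747 to 73578672), had a promoter peak at the annotated 5′ end in either replicate. With every transcript start, both still had no promoter peak in the replicated list. Ddc, which makes dopamine from L-DOPA, had 9.75 ± 3.48 kb of acetylated length and a promoter peak only when every transcript start was used, and Aldh1a1, Drd2 and Msx1 had 0.208 kb or less. Of 13 cholinergic, motor and serotonergic genes, 2 had a promoter peak (exact adjusted p = 0.0184): Ache, the acetylcholinesterase (signal values 4.94 and 8.33), and the LIM factor Isl1 (4.18 and 4.89). Tph2 (0.961 ± 0.796 kb) and Chat (0.152 ± 0.215 kb), enzymes of serotonin and acetylcholine synthesis, had no promoter peak. With the peak midpoint required, the same count had an exact adjusted p of 0.0548.

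Oligodendrocyte, microglia and erythroid genes had fewer promoter peaks than other genes, whereas the astrocyte, endothelial and pericyte lists did not pass the threshold. The microglia and erythroid lists have 1 CpG-rich promoter each and did not pass among CpG-rich promoters alone (both exact adjusted p = 1), and 23.6% of promoters that are not CpG-rich had a peak. A list with 1 CpG-rich promoter could not pass that test in either direction. Of 15 oligodendrocyte lineage genes, 3 had a promoter peak (exact adjusted p = 0.0272): the transcription factor Nkx2-2 (signal values 4.73 and 3.06), and the myelin genes Mbp (3.08 and 5.25) and Cnp (3.88 and 5.48). Sox8 (6.09 ± 1.01 kb; SD, n = 2) and Mog (4.81 ± 0.435 kb) had the longest acetylated lengths without a replicated promoter peak; Sox8 had one in replicate 2 alone (3.02) and was counted with a 2 kb window or every transcript start. This list no longer differed in replicate 2 alone (5 of 15, exact adjusted p = 0.169) or in replicate 1 alone (4 of 15, adjusted p = 0.0861), with a 2 kb window (5 of 15, adjusted p = 0.156), in the pooled list (5 of 15, adjusted p = 0.153), among the 50% of peaks with the highest signal value (3 of 15, adjusted p = 0.0533) or with the peak midpoint (3 of 15, adjusted p = 0.0644), and so passed in 3 of 9 alternatives. Of 15 astrocyte genes, 9 had a promoter peak (exact adjusted p = 0.674), and the nuclear factor I genes Nfib (39.5 ± 6.05 kb), Nfix (34.1 ± 3.07 kb) and Nfia (28.8 ± 3.14 kb), which drive gliogenesis, were the most acetylated, followed by Aldh1l1 (9.72 ± 2.22 kb, with a promoter peak only when every transcript start was used). Aqp4, Tnc, Gjb6 and S100b had 0.248 to 1.42 kb and no replicated promoter peak, and Tnc had one in replicate 1 alone (2.79). Of 16 microglia and macrophage genes, the lysosomal enzyme gene Hexb (6.13 and 2.83) and the complement gene C1qb (3.25 and 3.83) were the 2 with a promoter peak (exact adjusted p = 0.00521). Aif1 (4.13 ± 0.707 kb) and Cx3cr1 (4.56 ± 0.990 kb) had the longest acetylated lengths of that list, followed by Tyrobp (1.46 ± 0.0940 kb), all without a promoter peak. Of 16 endothelial genes, 4 had one (exact adjusted p = 0.0581): the glucose transporter gene Slc2a1 (10.4 and 9.08), and Kdr, Eng and Sox18, each with a promoter peak in replicate 2 and none in replicate 1. Pecam1, an endothelial adhesion molecule, had 5.37 ± 1.65 kb and a promoter peak only when every transcript start was used. The endothelial list passed as lower in replicate 1 alone (2 of 16, exact adjusted p = 0.00384), among the 50% of peaks with the highest signal value (1 of 16, adjusted p = 0.00247) and among peaks overlapping both replicate lists (1 of 16, adjusted p = 0.00147). Of 17 pericyte, meningeal and mesenchymal genes, 5 had one (exact adjusted p = 0.112): Pdgfrb, Foxc1, Foxd1, Twist1 and Vtn, whose peak (15.5 and 19.2) also held the TSS of Sarm1; Foxc2 (1.04 ± 0.0750 kb) had a promoter peak in replicate 2 alone. That list passed as lower with every transcript start (5 of 17, exact adjusted p = 0.0496) and among the 50% of peaks with the highest signal value (2 of 17, adjusted p = 0.00614). Of 14 erythroid genes, 1 had a promoter peak (exact adjusted p = 0.00278): Tal1 (9.89 and 20.1), which also stands in the GABAergic list. The erythropoietin receptor gene Epor (3.08 ± 0.0544 kb), Nfe2 (2.62 ± 0.129 kb) and Klf1 (0.584 ± 0.204 kb) had none.

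Few tissue genes of liver, muscle and skin had a promoter peak. A promoter peak was found at 2 of 16 liver genes (exact adjusted p = 0.00521), 3 of 15 cardiac muscle genes (adjusted p = 0.0272), 2 of 15 skeletal muscle genes (adjusted p = 0.00670) and 2 of 15 epidermal genes (adjusted p = 0.00670). These tests compare with all other genes, whereas the liver list has 0 CpG-rich promoters and the skeletal muscle and epidermal lists 1 each, and 23.6% of promoters that are not CpG-rich had a peak. Among CpG-rich promoters alone, the skeletal muscle and epidermal lists did not pass (exact adjusted p = 1 and 0.236). With 1 such promoter each, they could not have passed in either direction. Some counted genes shared the peak with the TSS of a neighbour: Foxa3 with Sympk and Trf with Gm20425 (liver), and Mylpf with Tbc1d10b and Actn3 with Zdhhc24 (skeletal muscle). The same held in other lists for Hes5 with Pank4 (progenitor), Ina with Nt5c2 (pan-neuronal), Gata3 with 9230102O04Rik (midbrain patterning and GABAergic), Mcm7 with Ap4m1 (cell cycle), Dusp1 with Ergic1 (immediate early), and Sdha with Ccdc127, Tbp with Psmb1 and Ubc with Gm10382 (housekeeping). The cardiac genes with a promoter peak were the myosin heavy chain gene Myh7 (signal values 18.6 and 18.7), the calcium channel gene Ryr2 (9.93 and 12.3) and the natriuretic peptide gene Nppa (5.59 and 5.48). Those of the epidermal list were Grhl3 (2.55 and 3.59) and the cornified envelope gene Lor (29.5 and 37.4), whose peak was not counted in a 500 bp window; whether this peak belongs to Lor cannot be settled from the lists. Other members had some acetylated length without a replicated promoter peak: Tat (2.53 ± 0.0898 kb; SD, n = 2) and Hnf1a (1.43 ± 0.228 kb) in liver, Myh6 (2.43 ± 0.289 kb) in heart, Acta1 (3.44 ± 0.151 kb) and Tnnt3 (2.10 ± 0.648 kb) in skeletal muscle, and Krt1 (1.75 ± 0.718 kb), Krt10 (1.46 ± 0.153 kb) and Ovol1 (1.26 ± 0.211 kb) in skin. Of these, Acta1 was counted with a 2 kb window, and Krt1 and Krt10 with every transcript start. The progenitor, pan-neuronal, midbrain patterning, dopaminergic, GABAergic and glutamatergic lists, joined before the data were examined, had a promoter peak at 85 of 105 genes (81.0%), and the liver, muscle, epidermal and erythroid lists at 9 of 74 (12.2%), a difference of 68.8 points (p = 5.38e-21, two-sided Fisher's exact test). The forebrain patterning list (9 of 20) and the cholinergic, motor and serotonergic list (2 of 13) were not part of this neural set. The cardiac list no longer passed the threshold with a 2 kb window (4 of 15, exact adjusted p = 0.0643), with the peak midpoint (3 of 15, adjusted p = 0.0644) or among the 50% of peaks with the highest signal value (3 of 15, adjusted p = 0.0533).

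Genes of general cell functions were acetylated to different degrees. All 18 housekeeping genes had a promoter peak (exact adjusted p = 7.38e-05), led by the elongation factor gene Eef2 (8.26 ± 0.464 kb; SD, n = 2), the actin gene Actb (7.58 ± 0.937 kb), Tubb5 (6.57 ± 0.928 kb) and Ubc (6.17 ± 0.170 kb), with Sdha, Rplp0, Hprt and Psmb2 at the low end (1.20 to 1.98 kb). Of 16 immediate early genes, which respond to neuronal activity and to stimulation of many other cells, 13 had one (exact adjusted p = 0.0342), with Junb (8.23 ± 1.17 kb), Btg2 (6.01 ± 2.13 kb), Ier2 (5.91 ± 0.00424 kb) and Dusp1 (6.83 ± 0.547 kb) leading. Egr2, Egr3 and Atf3 lacked it, although Egr3 had one in replicate 2 alone (2.76), and Fosl2 (1.84 ± 0.158 kb) was low but had it. Of 18 cell cycle genes, 12 had one (exact adjusted p = 0.285). The mitotic kinase gene Aurkb (7.71 ± 0.230 kb) and the replication licensing genes Mcm7 and Mcm2 (4.99 ± 0.783 and 4.38 ± 0.774 kb) had the longest acetylated lengths, followed by Ccnd1 (2.55 ± 0.534 kb). Mcm6 was low (0.534 ± 0.0247 kb) but had a promoter peak, whereas Mki67, Ccnb2 and Top2a had none in the replicated list. Aurkb and Top2a had one in replicate 1 alone (3.27 and 3.16), and they and Ccnb2 were counted in the pooled list. The immediate early list did not pass the threshold in 5 of 9 alternatives (exact adjusted p up to 0.173) or among CpG-rich promoters (10 of 12, adjusted p = 1), nor did the housekeeping list there (14 of 14, adjusted p = 0.670), while the cell cycle list did in the pooled list (15 of 18, adjusted p = 0.0272) and in replicate 1 alone (14 of 18, adjusted p = 0.0490). Among CpG-rich promoters, neither the immediate early nor the housekeeping list could have passed as higher, even with a peak at every promoter.

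Several lists of neuronal genes, and the progenitor and midbrain patterning lists, had more distal peaks than random lists. Pan-neuronal genes had 15.1 distal peaks per member, against 4.15 in random lists matched on territory (adjusted p = 0.00440, permutation test; the smallest p that 10000 random lists can give is 0.0002 before adjustment). Progenitor genes had 11.9 against 3.75 (permutation adjusted p = 0.00880), GABAergic genes 9.40 against 2.81 (adjusted p = 0.0176), glutamatergic and tectal genes 12.2 against 4.71 (adjusted p = 0.0242) and midbrain patterning genes 9.65 against 4.00 (adjusted p = 0.0405). Sox2 had 35 distal peaks, Otx2 had 19, Pax7 had 15, En1 had 14 and En2 had 10. Celf4 had 88 distal peaks and Meis2 had 33. The peaks were spread unevenly over members: Celf4 held 88 of the 332 distal peaks of the pan-neuronal list. Sox2 held 35 of the 237 of the progenitor list, and Id4 and Sox9, named after their values were seen, each held more than Sox2. At least 1 distal peak was assigned to 21 of 22 pan-neuronal and 19 of 20 progenitor genes. Forebrain patterning genes had 4.95 against 3.55 (permutation adjusted p = 0.492), dopaminergic genes 5.25 against 4.28 (adjusted p = 0.6001) and astrocyte genes 6.87 against 3.26 (adjusted p = 0.233). Hox genes had 0.0513 against 0.348 (permutation adjusted p = 0.0733). Oligodendrocyte genes (2.53 against 1.57), microglia (40 peaks over 16 members, against 1.53 per member), immediate early (3.31 against 1.82), cell cycle (2.11 against 1.56) and housekeeping genes (2.00 against 0.848) did not pass the threshold, nor did the cholinergic, endothelial, pericyte, erythroid, liver, cardiac muscle, skeletal muscle and epidermal lists (0.429 to 2.19 distal peaks per member). With every transcript start in use, the GABAergic and glutamatergic lists (both permutation adjusted p = 0.112) and the midbrain patterning list (adjusted p = 0.133) no longer passed, and the last also did not pass in the pooled list (adjusted p = 0.0697) or among the 50% of peaks with the highest signal value (adjusted p = 0.0651). Within 50 kb of the TSS, the astrocyte (4.40 against 1.57, permutation adjusted p = 0.00825) and immediate early lists (4.25 against 1.66, adjusted p = 0.00754) passed as higher, and the Hox list as lower (0.103 against 1.75, adjusted p = 0.00110). Neighbouring Hox genes share much of these windows, so the p-value of that list overstates the evidence. Random lists were drawn from all protein-coding genes, with or without a promoter peak, and were matched on territory alone. In the main setting, housekeeping genes had 2.36 times and astrocyte genes 2.10 times the distal peaks of random lists. Midbrain patterning genes had 2.41 times. An excess particular to neurons and progenitors was therefore not shown.

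Joining peaks within 10 kb gave 27203 clusters of acetylation. The largest, over Msi2, an RNA-binding protein of neural progenitors, held 139 kb under 123 peaks (chromosome 11, 88347185 to 88719523), with 89.5 kb covered in replicate 1 and 138 kb in replicate 2. Next were clusters over the transcriptional coactivator Zmiz1 (83.3 kb), the body of Ptprn2 with Mir153 (78.2 kb; nearest TSS Rapgef5), Gse1 (72.9 kb; nearest TSS Gins2) and the non-coding gene 9330198N18Rik (72.8 kb; nearest TSS Cstad). The imprinted neuronal gene Nnat followed with 66.0 kb, then a gene-dense region from Cbarp to Dazap1 on chromosome 10 (60.3 kb), Tcf7l2, an effector of Wnt signalling (48.4 kb), the corepressor Ncor2 (47.7 kb), and Pipox and Sez6 (47.3 kb). The remaining clusters of the first 15 lay over Zfhx3 (46.0 kb; nearest TSS Pmfbp1), the microRNA host gene Mir9-3hg (45.3 kb; nearest TSS Polg), Mir9-1 (41.6 kb; nearest TSS Rhbg), Dscaml1 (41.4 kb; nearest TSS Cep164) and Nr2f2 (40.6 kb).

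The widest single peak spanned 17.0 kb over Mir124a-1hg, the host gene of the neuronal microRNA miR-124 (chromosome 14, 64579697 to 64596655; nearest TSS Kif13b), with signal values of 34.3 in replicate 1 and 52.7 in replicate 2. Wide peaks also lay at Zfhx3 (17.0 kb), the tectal factor Lhx9 (15.9 kb), Tnrc18 (15.4 kb), Sox2 (15.3 kb), the Mir9-1 region near Rhbg (14.4 kb), Tfap2d (13.1 kb) and the Gata3 locus (12.5 kb). Of the others, a peak of 13.7 kb overlapped no annotated gene (nearest TSS Lrrc74a). A peak of 12.8 kb overlapped the non-coding gene 4930578M01Rik (nearest TSS Tuba1a, an alpha-tubulin gene). Of the 15 leading clusters, 9 and 8 stayed among the first 15 with joining distances of 5 and 20 kb, and 12 and 10 in replicate 1 and replicate 2 alone. The largest cluster held 63.1 kb with a joining distance of 5 kb and 89.5 kb in replicate 1 alone.

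Binding sites for RFX factors, which control genes of cilia, were 2.19 times as dense at distal peaks as in their flanks (95% interval 2.09 to 2.29). Sites for MEF2, a family of neuronal and muscle regulators, were 1.44 times as dense (1.30 to 1.58). Sites of the consensus YTAATTA, listed for LIM and POU homeodomain factors, were 1.17 times as dense (1.13 to 1.22). The scan counted sequences and cannot tell which factors bind them. The RFX, MEF2 and LIM and POU motifs, 3 of 16, had an interval above 1 and lay above all permutations of their letters. CTCF sites (2.86), NFI sites (2.33), ETS sites (1.66), ASCL1 and TCF E-boxes (1.59), HNF1 (1.32), EBF (1.31) and SOX sites (1.20) were also denser at peaks, but no more so than some permutations or with an interval reaching below 1. The proneural E-box (1.07), FOX (1.03), AP-1 (0.882), GATA (0.877), OTX and PITX (0.859) and HNF4 sites (0.805) were not called either; FOX sites lay above 19 of 20 permutations. Peaks had 47.6% GC against 44.4% in flanks and 16.5 CpG per kb against 9.81. Distal peaks here were those away from the annotated 5′ ends of protein-coding genes. Peaks at other transcript starts and at non-coding genes stayed among them. Promoters held 11943 replicated peaks in the main setting, and 15404 with every transcript start. No motif setting left these peaks out, so the ratios are not those of enhancers alone. The LIM and POU motif was not called in 500 bp windows (1.04, 95% interval 0.979 to 1.11), although it lay above 20 of 20 permutations there. The MEF2 motif was not called among the 50% of peaks with the highest signal value, where it lay above 19 of 20 permutations. HNF1, with 35 sites in peaks, was called in replicate 1 alone (1.64, 60 sites), and ETS in 500 bp windows (1.92) and among the 50% of peaks with the highest signal value (2.34). With permutations holding as many CG letter pairs as the consensus, the ASCL1 and TCF E-box, SOX, NFI and CTCF motifs were also called higher. They lay above all of their permutations there. The ASCL1 and TCF E-box, NFI and CTCF consensus sequences hold ambiguous letters that can match C or G. For them, the CpG content of matched sites was not made equal.

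**Figure D4:**
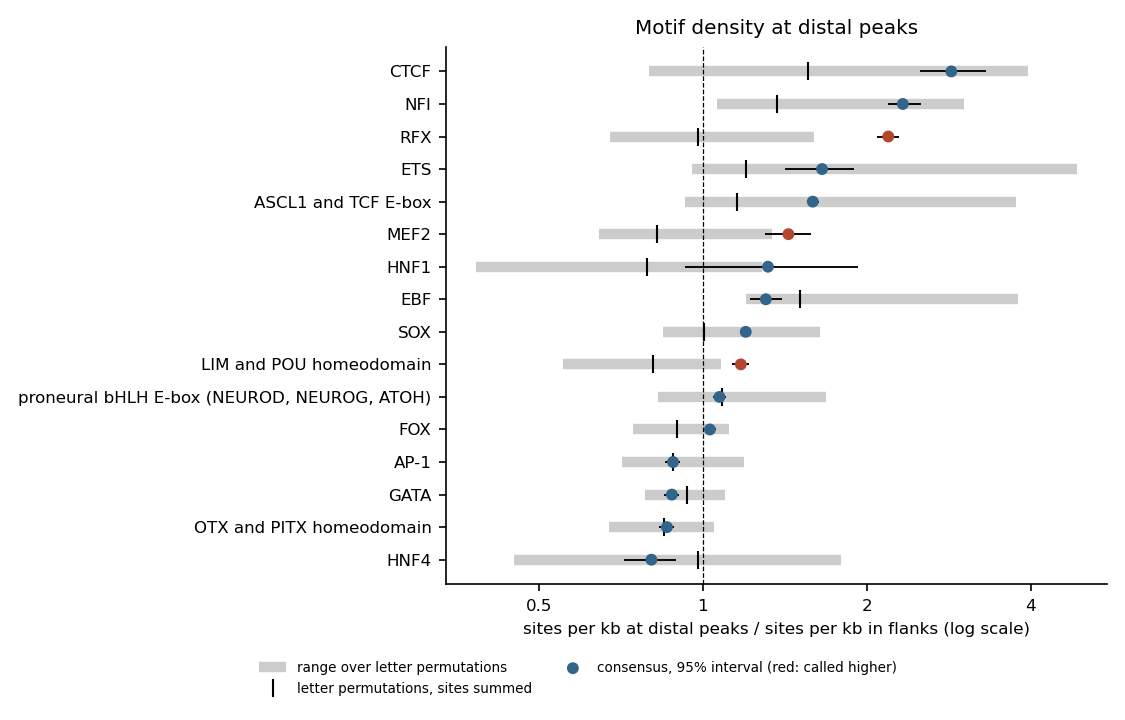
Site density at distal peaks over that in flanks (ratio, log scale) for 16 motif consensus sequences: points with 95% bootstrap intervals, grey bars for the range of their letter permutations and ticks for the permutations with sites summed. RFX (2.19), MEF2 (1.44) and the LIM and POU motif (1.17), in red, lay above all of their permutations.

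Chromosome X carried few peaks, although the X-linked neuronal and housekeeping genes of the lists were acetylated. Dcx, the microtubule protein of migrating neurons, had promoter signal values of 12.2 and 13.2, the synaptic vesicle gene Syp 12.3 and 8.04, Hprt 17.0 and 14.7, and Pgk1 13.1 and 16.9 (Dcx and Pgk1 were chosen after their values were seen). Chromosome X had 904 replicated peaks, or 5.29 per Mb, against 16.2 to 31.1 per Mb on the autosomes, and 0.954 per protein-coding gene against 1.55 to 3.84. Chromosome 11 was the densest per Mb, and chromosome 12 per gene. Chromosome Y had 6 peaks. The pools mixed sexes, and the share of each sex is not given in the sources used here. No p-value was computed for these densities, and explanations for the few peaks on chromosome X are weighed under the other observations.

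**Figure D5:**
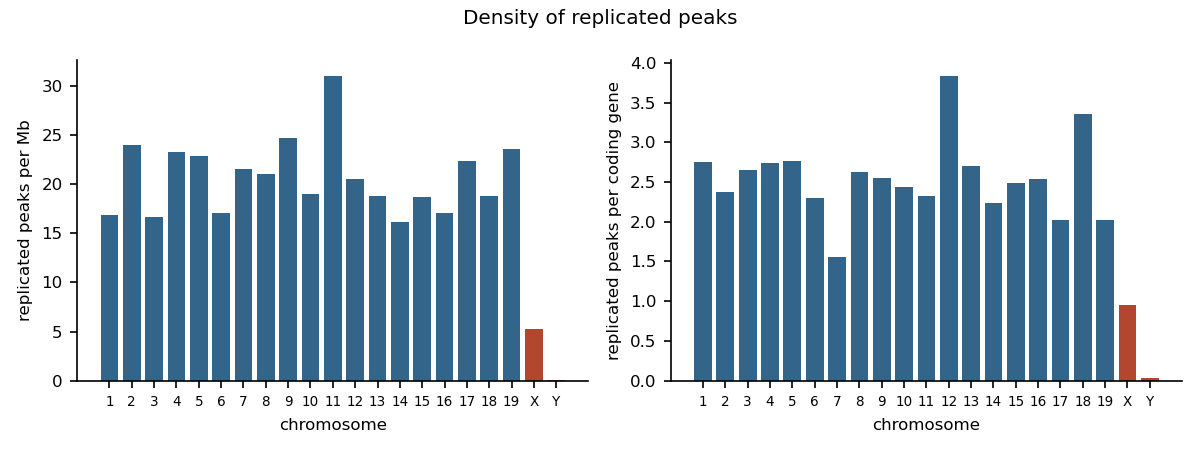
Replicated peaks per Mb (left) and per protein-coding gene (right) on each chromosome, with the sex chromosomes in red. Chromosome X, with 5.29 peaks per Mb and 0.954 per gene, lay below every autosome.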

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

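The restriction to CpG-rich promoters and the restriction to replicated peaks that overlap both replicate lists were chosen only after the result was seen. So were the permutations with as many CG letter pairs as the consensus. The neural lists kept their excess over the non-neural lists in all 9 alternatives run on whole lists (57.6 to 73.6 points), and the midbrain list kept its excess over the Hox list (55 to 75 points). The midbrain and forebrain lists differed by 20 to 25 points and never past the threshold (adjusted p 0.191 to 0.341). No gene list that passed in the main analysis passed in the opposite direction in an alternative, but the cell cycle list, which did not pass there, was higher in the pooled list and in replicate 1 alone and lower among CpG-rich promoters. The promoter share of peaks followed the list used: 15.98% to 18.1% without one replicate and 14.1% in the pooled list. It was 40.1% among the 50% of replicated peaks with the highest signal value and 26.3% among those overlapping both replicate lists. With a 2 kb window it was 24.9%, and with every transcript start at the main window of 1 kb it was 29.7%. Both settings count more sequence as promoter, but the amounts were not compared and the cause was not tested. Lists with an excess of promoter peaks numbered 6 in the main analysis, 2 with the peak midpoint, which leaves out wide peaks reaching into the promoter from beside it, and 0 among CpG-rich promoters, where 88.2% of all genes had a peak. There the pan-neuronal (12 of 12, exact adjusted p = 0.670), progenitor, GABAergic, glutamatergic, immediate early and housekeeping lists no longer passed, nor did the microglia, erythroid, skeletal muscle and epidermal lists, with 1 CpG-rich member each. None of these lists could have passed there: for the first 6 a peak at every promoter was not enough, and for the others 1 member was too few. Their loss in this setting therefore decides nothing about the effect of CpG content. Promoters that are not CpG-rich do bear on it for the neural lists joined, which include the midbrain patterning and dopaminergic lists. There 31 of 43 had a peak, against 23.6% of all such promoters. These values argue against the CpG class as the whole cause of the excess in that set. Single lists were not tested there. Lists with an excess of distal peaks numbered 5, 2 with every transcript start, and 7 within 50 kb of the TSS, where the astrocyte and immediate early lists were added; the cause was not tested. The number of lists with fewer distal peaks than random lists was 0, but 1 (the Hox genes) with a 500 bp window, with the peak midpoint, in the pooled list and within 50 kb of the TSS, and 0 to 1 without one replicate; the cause was not tested. Motifs called higher numbered 3, and 7 with permutations of as many CG letter pairs, which added the ASCL1 and TCF E-box, SOX, NFI and CTCF. The ratios of these motifs were the same in both settings. The highest ratio among their permutations fell from 3.76 to 1.44, 1.64 to 1.12, 3.02 to 1.61 and 3.95 to 2.44, in that order. The added calls therefore came from leaving out permutations with another number of CG letter pairs, apart from the new draw of permutations. The signal values of the replicates had a rho of 0.789, against 0.833 for −log10 p and 0.871 for peaks paired by reciprocal overlap of 50%; the cause was not tested. The density on chromosome X was 5.29 peaks per Mb, and 7.54 to 7.76 without one replicate, since each replicate list is longer than the replicated list. Unknown depth limits every absence: a gene without a peak passed no threshold in these lists, which does not show that it was unacetylated. Cell types of the midbrain were not separated, so such a gene can still be acetylated in part of the cells. The difference in peak number between the replicates cannot be divided into depth and biology.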

Other observations

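The tests on the pooled list, on −log10 p at matched signal values, on the number of strong peaks, on peaks per gene and on distal peaks of chromosome X were chosen only after the result was seen; the tests on CpG-rich promoters and on signal values of chromosome X were added after other results were seen but with predictions written before their own results. The series holds 1 group, so no biological explanation was tested for any pattern.

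CpG-rich promoters, found at 9725 genes (44.4%), carried a peak in 88.2% of cases, and the other promoters in 23.6% (2873 of 12186). Among CpG-rich promoters alone, some lists stood below the rest: the Hox genes (0 of 24, adjusted p = 9.13e-22, two-sided Fisher's exact test over 22 lists), the cholinergic, motor and serotonergic genes and the oligodendrocyte genes (1 of 6 each, adjusted p = 0.000895), the cell cycle genes (8 of 14, adjusted p = 0.0189), the cardiac genes (1 of 4, adjusted p = 0.0262) and the forebrain patterning genes (8 of 13, adjusted p = 0.0471). The Hox genes lie side by side in clusters and are not independent, so their p-value overstates the evidence. Other lists stood below the rest without passing the same test. Among them were the midbrain patterning genes (10 of 14, exact adjusted p = 0.201) and the dopaminergic genes (7 of 10, exact adjusted p = 0.236). The midbrain and forebrain lists were not compared directly among CpG-rich promoters, and their difference over all promoters did not pass. The cell cycle genes without a replicated promoter peak included Mki67, the proliferation marker, and Top2a, the topoisomerase of dividing cells, which had a peak in replicate 1 alone (signal value 3.16). The liver list had no CpG-rich promoter to count.

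Some genes outside the fixed rule were named after their values were seen. Id4 and Sox9, regulators of progenitors and glia, had 61 and 45 distal peaks, more than the 35 of Sox2. With Sox2, they held most of the 237 distal peaks of the progenitor list. The dopaminergic regulators Lmx1b (2.45 and 3.46) and Foxa2 (4.00 and 3.79), and the oligodendrocyte factor Olig2 (3.25 and 3.62), had weak promoter peaks in both replicates without a promoter peak in the replicated list. The replicated peaks that overlapped a peak of 1 replicate were weaker than those overlapping both (median signal value 2.94 against 4.44) and lay less often at promoters (5.59% against 26.3%).

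Genes of the progenitor, pan-neuronal, midbrain, dopaminergic, GABAergic and glutamatergic lists had more promoter peaks than genes of liver, muscle, skin and blood, by 68.8 points, a set without the forebrain (9 of 20) and cholinergic, motor and serotonergic lists (2 of 13). If CpG content made this difference, it would be gone among CpG-rich promoters, yet there 54 of 62 genes of this neural set and 2 of 6 non-neural genes had a peak (p = 0.00738, two-sided Fisher's exact test), and among the other promoters 31 of 43 and 7 of 68 did (p = 2.06e-11). If weak peaks of non-neural genes had been lost on the way to the replicated list, the longer pooled list would narrow the gap, yet it was 73.6 points there. The pooled list also starts at a −log10 p close to 2, so it cannot show whether peaks were lost below that threshold. The CpG-rich comparison rests on 6 non-neural genes. A difference in cell type remains a hypothesis that a single tissue cannot test.

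Replicate 2 had more peaks than replicate 1. A lenient threshold that adds weak peaks is argued against by the ratio of peak numbers at a −log10 q of at least 5, which was 1.24, above the 1.11 for all peaks. A deeper replicate 2 may be part of the cause: at 5728 peaks with signal values within 5% of each other, the −log10 p of replicate 2 was a median of 1.12 times that of replicate 1, and 1.101 to 1.14 times on each of the 19 autosomes. The depth of the controls or a different enrichment stays open, since the lists hold no read counts.

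Chromosome X had few peaks. Low gene density as the whole cause is argued against by the 0.954 peaks per gene, below every autosome. A smaller share of CpG-rich promoters (23.9% of X-linked genes against 45.7%) may account for few promoter peaks, since CpG-rich promoters carried a peak in 86.3% of cases on X and 88.3% on the autosomes (p = 0.350, two-sided Fisher's exact test, which does not show the shares to be equal), but not for the distal peaks, whose density on X was 0.189 times that of the autosomes. A lower signal per locus is a candidate explanation: at called CpG-rich promoters the median signal value on X was 0.829 times that of the autosomes, and below every autosome in both replicates. Whether this comes from a single X in males, from X inactivation in females or from mapping on X was not tested.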
